A study of Homo sapiens with 5 samples.

How the data were processed

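Chromatin was profiled in Huh 7, an established human hepatocellular carcinoma line, left untreated per the labels. The series holds 5 libraries, 1 for each of H3K27ac, H3K4me1 and H3K4me3 chromatin immunoprecipitation (ChIP-seq), ATAC-seq, which reads open chromatin by transposase insertion, and input DNA. Lists of peak summits were used for 4 of these libraries, and the input library was not analysed here. Each assay had 1 library, so no difference carries a replicate check and no p-value is given.

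The submitters' processing notes name the genome build hg38 and the tools Bowtie, Picard, deepTools and MACS2, without versions, roles or order. Settings of the peak caller, read depth and the use of the input as a control are not given in the sources used here. The deposited lists have no header and follow the layout of MACS2 summits, with 1 position of 1 bp per peak. The deposited score of each summit is a −log10 value of the authors' peak caller, by default of a q-value, although a p-value cannot be ruled out. The lowest score of each list lay just above 1.30, which is −log10 of 0.05. These scores depend on read depth, so they were used to describe, rank or filter the summits of each list, and no comparison between marks rests on them. The alternative with a minimum of 10 applied the same value to every list and so kept different shares of them. Peaks were called per library, as the peak names show. The ChIP peak names carry the line's name and a replicate mark, whereas the ATAC peak names begin with another prefix. The identity of the ATAC library rests on its label.

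Read depth was unknown, and the number of summits stands in its place. Summits on chromosomes 1 to 22 and X were used. Gene positions came from a RefSeq table of the GRCh38.p14 assembly, which shares its primary coordinates with hg38, and positions are 1-based. From 38151 protein-coding and lncRNA entries, 426 that broke the positional order of their chromosome, and were taken to lie on scaffolds, were left out. This kept 19821 protein-coding and 17904 lncRNA genes. The table gives no strand, exons or transcript positions. A gene end therefore means a place within 1000 bp of either end of a gene, where the plan had named transcription start sites, and gene body replaces exon and intron. No genome sequence was used, so the planned search for 21 consensus motifs was not run.

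Summits of different lists were called co-occurring when they lay within 1000 bp. Observed shares were set beside 100 random placements of the second list, with the same number per chromosome between its first and last summit. Shares have exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. Neighbouring summits are not independent, so these intervals are narrow. Distal summits were those more than 1000 bp from every gene end. For each gene, distal summits within 50000 bp of either end were counted. H3K27ac summits more than 2000 bp from a gene end were stitched over gaps of up to 12500 bp. The clusters were ranked by summed score, with a cutoff where the slope of the scaled rank curve passed 1. This follows the rule of the ROSE method on scores in place of read signal, so the clusters are not super-enhancer calls.

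Gene lists, settings, most alternatives and the rule for named genes were fixed before the data were examined, except that gene ends took the place of start sites. The 16 lists held 243 different genes, all of which matched a symbol in the table. A list's share or median was described by its percentile among 10000 random lists of protein-coding genes. Random lists were matched on decile of gene length at gene ends, and on local gene density and length tertile at distal sites. Values above 95 or below 5 were treated as standing apart, over 16 lists per measure and without correction for their number. Ties counted in equal parts to each side, so a percentile of 0 means that no random list was as low. DES and VIM are among the genes that stand in a pair of lists.

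The rule for named genes took, in each list, the 2 members with the highest H3K27ac score at a gene end among those with both H3K4me3 and H3K27ac there, and the first member in alphabetical order with neither. It also took the 10 highest-ranked clusters with the genes they overlap or, failing that, the nearest gene. In 4 liver lists it took the 2 members with the most distal H3K27ac summits, and it took the 5 highest-scoring distal ATAC summits with H3K27ac and H3K4me1. Some genes that the rule takes are not reported here. Other genes are named only as chosen after their values were seen.

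Alternatives covered windows, score minimums, collapsing of close summits, the random background, distances and the stitching rule. The functions were checked on simulated lists. A planted overlap over 59492 simulated ATAC summits gave 34.85% where 34.8% was due. Of 200 unchanged lists of 20 genes drawn from 19821, 11.5% fell outside the 5th to 95th percentile, where 10% was due. Of 200 lists raised from 50% to 85%, 97% were found above the 95th percentile. Marks in these simulations were set gene by gene, without regard to position or length. The check therefore does not cover lists whose members are neighbours and share summits. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.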

Results

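The series mapped chromatin state in Huh 7 hepatocellular carcinoma cells on the hg38 genome, with 1 library per assay. H3K4me3 is a histone mark of promoters, H3K4me1 of enhancers and H3K27ac of active promoters and enhancers, while ATAC-seq reports open chromatin. On chromosomes 1 to 22 and X the lists held 126231 H3K4me1, 83323 H3K27ac, 59492 ATAC and 44801 H3K4me3 summits. The median −log10 value was 4.55 for H3K4me1, 7.33 for H3K27ac, 8.06 for ATAC and 14.0 for H3K4me3. A value of 10 was reached by 11.4% of H3K4me1, 41.7% of H3K27ac and ATAC and 55.7% of H3K4me3 summits. These values depend on read depth, so differences between lists in them do not compare the marks. Neighbouring summits were closest in the H3K4me1 list, at a median spacing of 2676.5 bp, and farthest apart in the ATAC list, at 23028 bp.

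Open chromatin and the histone marks lay close together more often than under random placement, and the share of open sites with each mark changed with position. Of all ATAC summits, 53.0% (95% interval 52.6 to 53.4) had an H3K27ac summit within 1000 bp, against 5.65% under random placement. At gene ends, 83.8% of ATAC summits had H3K4me3 and 78.2% had H3K27ac, whereas 20.1% had H3K4me1. At distal sites the shares were 47.1% for H3K4me1, 44.0% for H3K27ac and 32.4% for H3K4me3. The lists differ in length, and over random placement the distal order was the reverse, at 10.8-fold for H3K4me3, 7.92-fold for H3K27ac and 5.66-fold for H3K4me1. H3K4me1 lay beside 28.0% of H3K27ac summits at gene ends and 73.2% at distal sites. Distal H3K27ac summits had ATAC in 38.1% and H3K4me3 in 28.7% of cases. Over random placement the distal ratios were 8.68-fold for H3K4me1, 9.11-fold for H3K4me3 and 9.45-fold for ATAC. A ratio to random placement has a lower ceiling for a longer list, such as H3K4me1. Neither these ratios nor those of distal ATAC summits therefore rank the marks.

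Among pairs over all positions, H3K4me3 summits had H3K27ac in 66.7% of cases (11.3-fold over random placement) and ATAC in 66.1% (16.1-fold). H3K27ac summits had H3K4me1 in 62.6% (62.3 to 63.0), 7.45-fold over random placement. H3K4me1 had H3K4me3 beside 15.5% of its summits (5.10-fold). Around open gene ends the nearest H3K27ac summit within 2000 bp lay at a median of 208 bp from the ATAC summit and the nearest H3K4me3 summit at 259 bp. The nearest H3K4me1 summit lay farther out, at 987 bp (quartiles 555.5 and 1409 bp). Of 15630 such ATAC summits, 6171 had an H3K4me1 summit in that range, against 12590 for H3K27ac and 13808 for H3K4me3. Scattered summits would also have a median near the middle of the range, so 987 bp need not be a characteristic distance. Around distal ATAC summits the median distances within 2000 bp were 223 bp for H3K27ac, 208 bp for H3K4me3 and 357 bp for H3K4me1. The share of H3K27ac summits with H3K4me1 fell to 18.6% when every list was restricted to scores of at least 10, a step that kept 14416 of the H3K4me1 summits, and to 28.4% with a window of 250 bp.

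Relative to random placement, H3K4me3, open chromatin and H3K27ac gathered at the ends of genes, and H3K4me1 did so least. Gene ends held 37.5% (37.1 to 38.0) of H3K4me3 summits, 26.3% of ATAC summits and 23.3% of H3K27ac summits, which was 7.46-fold, 5.64-fold and 4.84-fold over random placement. They held 6.43% (6.30 to 6.57) of H3K4me1 summits, 1.40-fold over random placement. Gene bodies held 65.9% of H3K4me1 summits, against 52.5% under random placement (1.25-fold). They also held 51.3% of H3K27ac, 42.1% of ATAC and 41.5% of H3K4me3 summits, more than gene ends did. Those shares were 0.978-fold, 0.805-fold and 0.793-fold over random placement. H3K4me1 reached its highest ratio, 1.66, between 1000 and 2000 bp from a gene end. H3K4me3 summits at gene ends had a median score of 60.6, against 6.04 in gene bodies. For H3K27ac these medians were 24.5 and 5.74, for ATAC 16.5 and 6.78, and for H3K4me1 4.36 and 4.55.

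Among 11374 protein-coding genes longer than 5000 bp with H3K4me3 at an end, 94.6% carried it at 1 end only. With a gene-end window of 2500 bp the share of H3K4me1 summits at gene ends was 15.7%, and with 500 bp it was 3.13%. Only summits with scores of at least 10 put 56.9% of H3K4me3 at gene ends.

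**Figure D1:**
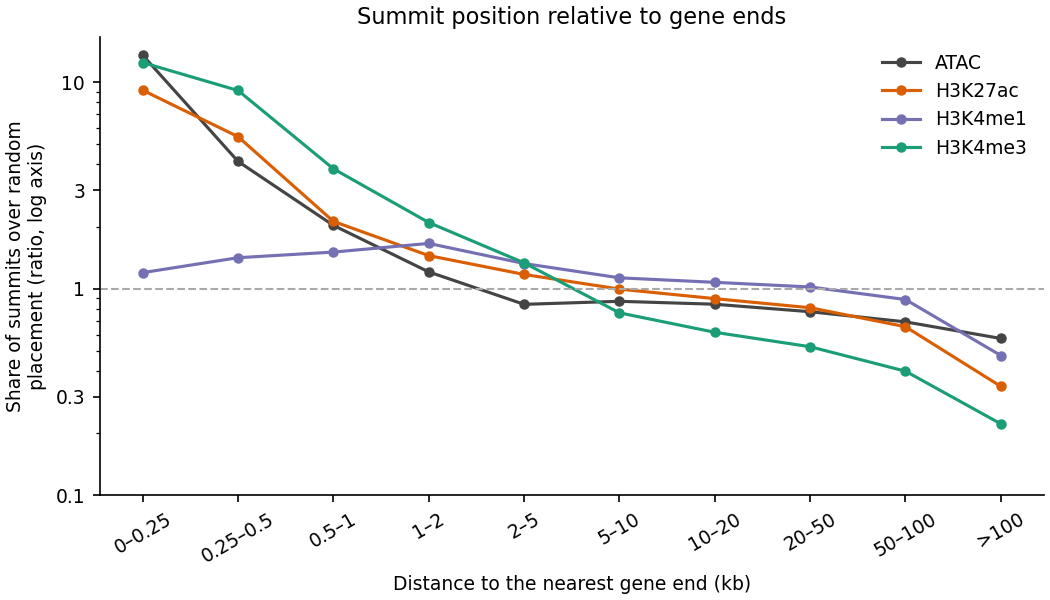
Share of each list's summits by distance to the nearest gene end (kb) as a ratio to 100 random placements, on a log axis, with 1 library per line. ATAC and H3K4me3 reached ratios of 13.5 and 12.5 within 250 bp, whereas H3K4me1 stayed at 1.196 there.

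Most protein-coding genes carried the marks of an active promoter at an end, and many others carried no summit at all. Of 19821 genes, 10797 (54.5%, 53.8 to 55.2) had both H3K4me3 and H3K27ac, and for 10698 these marks lay at the same end. Open chromatin was added at 10340 genes, or 52.2%. H3K4me3 without H3K27ac was found at 1955 genes (9.86%), and H3K27ac without H3K4me3 at 888 genes (4.48%). No summit of any list was found at the ends of 5337 genes (26.9%).

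The most frequent state combined ATAC, H3K27ac and H3K4me3 without H3K4me1, at 8094 genes (40.8%). H3K4me1 lay at the ends of 17.5% of genes, and at 827 genes it came without H3K4me3. The share of genes with both H3K4me3 and H3K27ac ranged from 40.8% with a 500 bp window to 61.3% with 2500 bp.

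Genes of the cell cycle and of general cell maintenance carried promoter marks almost without exception, while most genes of adult liver metabolism and most endothelial markers lacked them. All 16 cell cycle genes had H3K4me3 and H3K27ac at a gene end (100%, 79.4 to 100), above the 99th percentile of length-matched random lists at 99.99. Housekeeping genes followed with 13 of 15 (percentile 99.645). Only 4 of 24 genes of mature hepatocyte metabolism had both marks (16.7%, 4.74 to 37.4, against 58.4% in random lists), and no random list was as low. Endothelial markers had both marks at 0 of 12 genes (upper bound 26.5%). Gene positions carry no strand, so marks at a gene end may lie opposite the start or belong to a neighbouring gene.

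The genes for secreted products of hepatocytes stood apart from random lists in open chromatin, H3K27ac and H3K4me1 at their ends, and not in H3K4me3 or in H3K4me3 with H3K27ac. Of 22 genes for plasma proteins, 15 had both marks (68.2%, 45.1 to 86.1, percentile 94.15), 20 had ATAC at a gene end (percentile 99.955), 17 had H3K27ac (98.235), 16 had H3K4me3 (88.47) and 11 had H3K4me1 (99.96). F2, which encodes prothrombin (11:46719213 to 46739506), had an H3K27ac score of 101.9 and an H3K4me3 score of 14.6. VTN, which encodes vitronectin (17:28367284 to 28370307), had an H3K27ac score of 84.1. FGB, the fibrinogen beta chain (4:154562980 to 154572807), had neither mark within 1000 bp of its ends. An H3K4me3 summit of score 52.7 lay inside the gene at 4:154564327, nearer the lower-coordinate end. ATAC scored 4.48 at that end (4:154562944) and 12.1 at the opposite end (4:154572374). The list passed the 95th percentile with a 2500 bp window, at 99.745, and fell to 47.57 with scores of at least 10.

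Of 20 hepatocyte transcription factors, 9 had both marks (percentile 22.36), 16 had ATAC and 8 had H3K4me1 (percentile 99.08). NR0B2, a corepressor in bile acid control, scored 121 for H3K27ac and 13.6 for H3K4me3. FOXA2, a pioneer factor of endoderm, had neither mark at its ends but an ATAC score of 27.1 and 2 H3K4me1 summits. The position of this list depended on the window, and with 2500 bp its percentile was 99.185.

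Among the 4 marked genes of mature hepatocyte metabolism, TAT, a tyrosine-degrading enzyme, scored 59.0 for H3K27ac and 80.3 for H3K4me3, and HPD, which acts in the same pathway, scored 42.3 and 73.6. These H3K27ac summits lay outside the gene spans, at 16:71565318 for TAT and 12:121889018 for HPD. Whether they mark these genes' own promoters was not determined. ADH1B, an alcohol dehydrogenase, had neither mark and an ATAC score of 3.56. The percentile stayed at or below 0.085 in every alternative tried. Fetal liver and oncofetal genes had both marks at 3 of 16 members (18.8%, 4.05 to 45.6, percentile 0.175), with H3K27ac alone at 6 and H3K4me1 at 7 (percentile 99.07). This low position was lost with a 2500 bp window, where the percentile was 51.01, and with marks counted anywhere in the gene, where it was 71.085. LIN28B, a repressor of let-7 maturation, scored 45.1 for H3K27ac and 118 for H3K4me3, and the imprinted gene PEG10 scored 64.6 and 77.9. AKR1B10, an aldo-keto reductase, had neither. AFP, chosen after its values were seen, had H3K27ac with a score of 4.13 at its end and no H3K4me3 there.

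Sterol synthesis and uptake genes had both marks at 12 of 15 members (percentile 92.965, and 95.22 to 99.635 in the 4 alternatives). The desaturase gene SCD had an H3K27ac score of 116 at a gene end. FDFT1, the gene for squalene synthase, had neither mark. Among housekeeping genes, GAPDH, which encodes a glycolytic enzyme, scored 133 and the translation factor gene EEF1A1 scored 114. Among cell cycle genes E2F1 scored 101 and FOXM1 90.8, both encoding regulators of cycle genes. Wnt target genes had both marks at 6 of 13 members (percentile 25.36). H3K4me1 lay at the ends of 5 Wnt targets (percentile 96.255). SP5 scored 57.3 and RNF43, a ubiquitin ligase that restrains Wnt receptors, 51.5, whereas LEF1 had neither mark.

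Among markers of other liver cell types, stellate, leukocyte and endothelial lists lay below the 5th percentile and cholangiocyte markers did not, and the difference between lists was not tested. Cholangiocyte markers had both marks at 6 of 12 members (percentile 42.015), among them SOX9 with an H3K27ac score of 51.7 and the anion exchanger gene SLC4A2 with 75.4, while the water channel gene AQP1 had neither. H3K4me1 lay at the ends of 5 cholangiocyte markers (percentile 97.14). Hepatic stellate and mesenchymal markers had both at 2 of 12 (percentile 0.27), namely RGS5 at 46.6 and LUM at 25.8, and the collagen gene COL1A1 had neither. The RGS5 summits lay outside the gene, at 1:163322107 for H3K27ac and 1:163322408 for H3K4me3. A neighbouring gene's promoter was not separated from them. The stellate list passed the 5th percentile with a 2500 bp window, at 5.90, and with marks anywhere in the gene, at 7.765. Leukocyte markers had both at 3 of 14 (percentile 1.14), with SPI1 at 19.8 and CD3E at 18.7, and the macrophage gene CD163 had neither. The SPI1 summit, 11:47355212, lay by the lower-coordinate end of the gene and the CD3E summit, 11:118315640, by the higher-coordinate end. Whether these ends hold the promoters was not determined. No endothelial gene had both, and CDH5, an endothelial cadherin gene, had neither.

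Neuronal and skeletal muscle genes had fewer promoter marks than random lists, and homeobox genes did not stand apart. Neuronal genes had both marks at 3 of 14 members (percentile 0.72), including TUBB3 at an H3K27ac score of 43.4 and SYT1 at 17.1, and CAMK2A had neither. Skeletal muscle genes had both only at CKM, at 8.39 (1 of 12, percentile 0.145), and ACTA1 had neither. Homeobox genes had both at 5 of 16 (percentile 14.45), with HOXA9 at an H3K27ac score of 6.99, and DLX5 had neither. With scores of at least 10 the homeobox percentile was 0.205. Epithelial-mesenchymal genes had both at 8 of 13 (percentile 67.845), with the fibronectin gene FN1 at 75.4 and the tight junction gene CLDN1 at 73.9, while the cadherin gene CDH2 had neither.

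**Figure D2:**
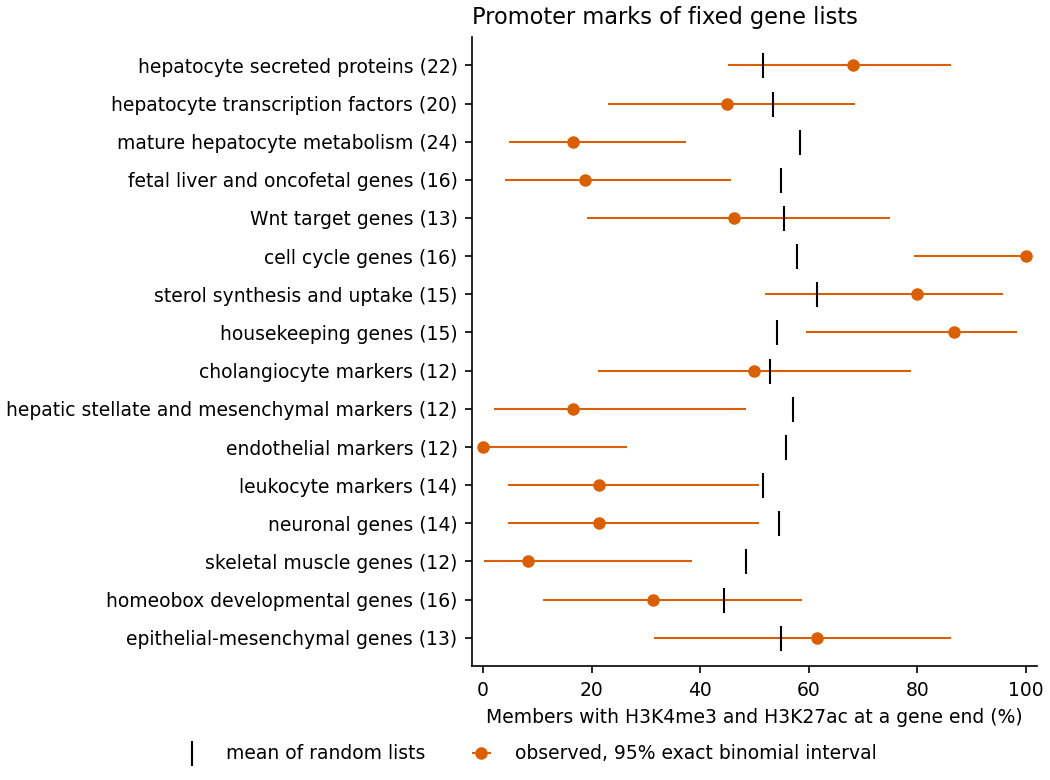
Share of each list's members (%) with H3K4me3 and H3K27ac at a gene end, with exact 95% binomial intervals of 1 library per mark and list sizes in brackets. Black bars give the mean of 10000 length-matched random lists, and cell cycle genes at 100% and endothelial markers at 0% mark the extremes.

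Around hepatocyte transcription factors, secreted protein genes and fetal liver genes, H3K27ac and H3K4me1 summits were denser than around matched random genes. Within 50000 bp, hepatocyte transcription factors had a median of 11.5 distal H3K27ac summits (8 to 20), fetal liver and oncofetal genes 10 (5 to 18) and secreted proteins 8.5 (3 to 14). Matched random lists had a median of 2, and these lists lay at percentiles of 100, 100 and 99.995. Epithelial-mesenchymal genes had a median of 10 (0 to 23, percentile 99.97). Of these, the epithelial genes CDH1, CLDN1, KRT8, KRT18 and OCLN, named after their values were seen, had 14 to 29. The other members had 0 to 12. Mature hepatocyte metabolism genes had 3 (1 to 7, percentile 79.14), and endothelial markers had 0 (0 to 7, percentile 0.495).

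HNF4A, a nuclear receptor of hepatocyte differentiation (20:44355699 to 44434596), had 40 distal H3K27ac and 41 distal H3K4me1 summits. PROX1, a homeobox factor of liver development (1:213983151 to 214041510), had 36 and 44, without H3K4me3 or H3K27ac at its ends. Among fetal liver genes, GPC3, a cell-surface glypican (X:133535745 to 133985594), had 30 H3K27ac summits and IGF2BP1, an RNA-binding protein gene (17:48996558 to 49056145), 22. Among metabolism genes, CYP1A2, a cytochrome P450 gene, had 12 and TAT 11, and 6 of 24 members had none. The neighbouring genes FGA and FGG, for the alpha and gamma chains of fibrinogen, had 27 each, and FGB had 27. These counts overlap, because the 3 genes lie within 50000 bp of each other.

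Distal ATAC summits followed for transcription factors (median 4.5, percentile 99.995), fetal liver genes (5, percentile 99.985), secreted proteins (3, percentile 98.905), epithelial-mesenchymal genes (4, percentile 98.3) and cholangiocyte markers (3.5, percentile 97.465). Homeobox genes had a median of 4 distal ATAC summits (percentile 99.975) with 1.5 for H3K27ac (percentile 26.24) and 1 for H3K4me1 (percentile 3.485). Cholangiocyte markers reached 12.5 for H3K4me1 (percentile 99.56) and 5.5 for H3K27ac (percentile 94.06). For H3K27ac, the percentiles were 91.33 for Wnt targets, 90.805 for cell cycle, 63.765 for sterol, 91.165 for housekeeping, 77.45 for stellate, 26.43 for leukocyte, 11.355 for neuronal and 87.685 for muscle genes. Distances of 20000 or 100000 bp left the 3 liver lists with the most summits above the 99th percentile, and the endothelial list rose to 9.075 at 20000 bp.

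**Figure D3:**
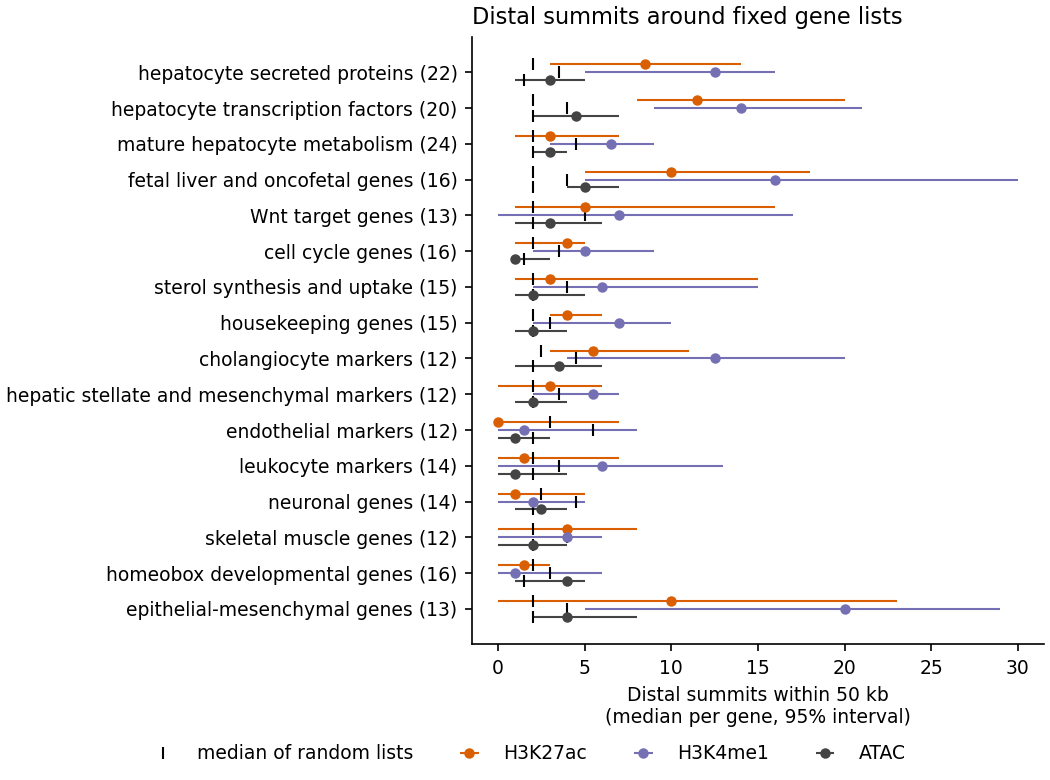
Median number of distal H3K27ac, H3K4me1 and ATAC summits within 50 kb of a gene, per list, with distribution-free 95% intervals over members and list sizes in brackets. Black bars give the median of 10000 matched random lists, and transcription factors (11.5), fetal liver (10) and secreted protein genes (8.5) lay above it for H3K27ac.

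**Figure D4:**
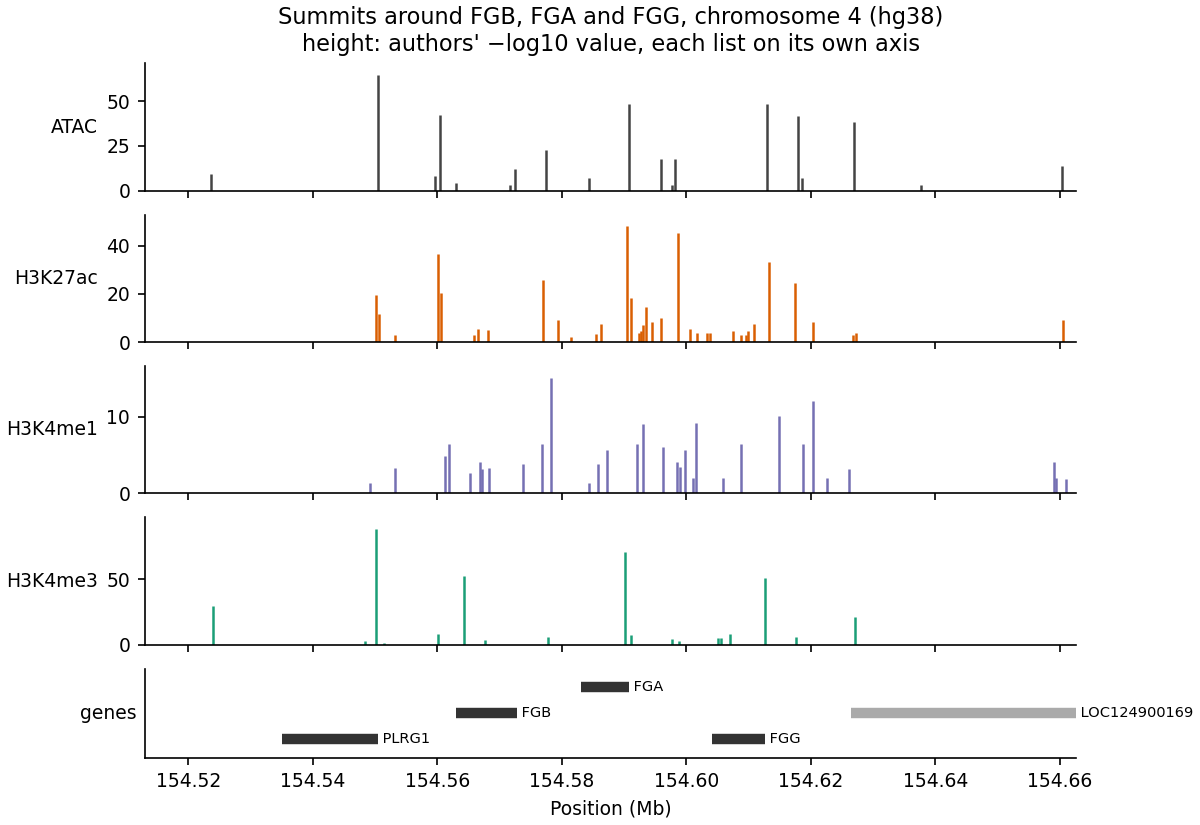
Summits of the 4 lists over 4:154512980 to 154662656 (position in Mb), with height as the authors' −log10 value on a separate axis per list and genes as bars (black protein-coding, grey lncRNA). The region held 37 H3K27ac, 32 H3K4me1, 19 ATAC and 18 H3K4me3 summits.

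Distal open sites carried enhancer-type marks, H3K4me3, both or no mark. Of 43862 distal ATAC summits, 30.6% (30.1 to 31.0) had both H3K27ac and H3K4me1, against 0.476% under random placement of the histone lists. H3K4me1 without H3K27ac, the textbook state of primed enhancers, was found at 16.5% (random 7.88%). H3K4me3 was found at 32.4% (random 2.998%). These classes overlap, since 13.4% of sites had all 3 marks, and 17.2% had H3K27ac and H3K4me1 without H3K4me3. No histone summit was found at 33.1% (32.7 to 33.6), against 84.0% under random placement. Each histone list was placed separately, which also breaks the pairing of the marks with each other. The gap between 30.6% and 0.476% therefore partly reflects that pairing. Taken singly at these sites, H3K27ac was 7.92-fold and H3K4me1 5.66-fold over random placement.

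Sites with H3K27ac and H3K4me3 but without H3K4me1 had a median ATAC score of 13.3, and sites without a histone summit 4.72. From the lowest to the highest of 4 equal groups by ATAC score, the unmarked share was 53.2%, 40.4%, 26.2% and 12.7%, and the share with H3K4me3 was 15.6%, 22.1%, 35.6% and 56.2%. The highest-scoring sites with H3K27ac and H3K4me1 also had H3K4me3 within 1000 bp. They lay at 1:236097210, 32120 bp from NID1 (ATAC score 98.2), at 11:67805786, 6223 bp from LOC112268076 (86.6), and at 11:67239913 within KDM2A (83.9). The others lay at 1:244461477 within CATSPERE, 9417 bp from ADSS2 (83.9), and at 4:52722382, 20171 bp from ERVMER34-1 (77.7). Transcript starts away from gene ends were not separated from these sites. With scores of at least 10 in every list, the share with H3K27ac and H3K4me1 was 12.4%, and with a 500 bp window it was 18.8%.

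**Figure D5:**
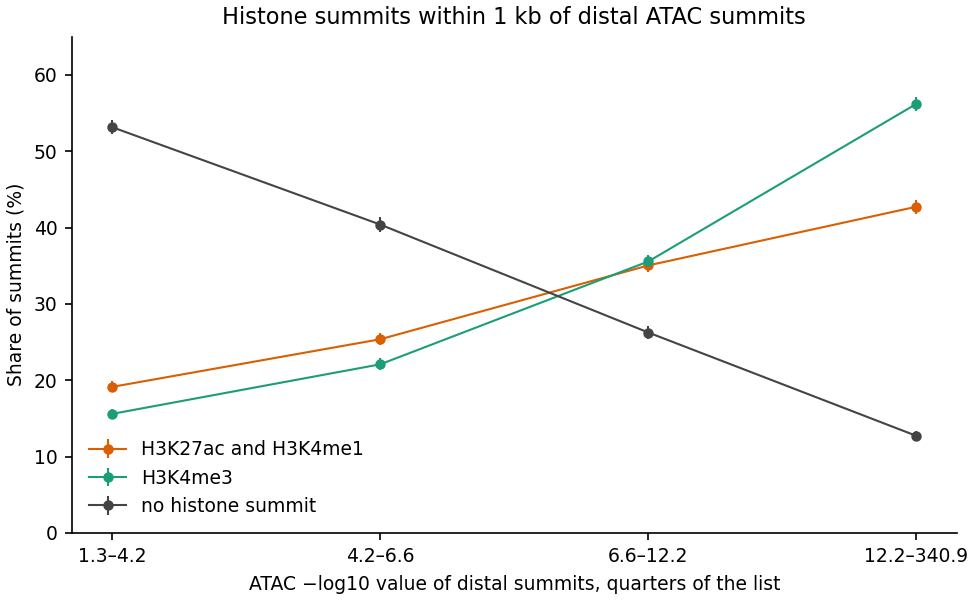
Share of distal ATAC summits (%) with H3K27ac and H3K4me1, with H3K4me3, or with no histone summit within 1 kb, in overlapping classes and 4 equal groups by ATAC −log10 value, with exact 95% binomial intervals and 1 library per assay. The unmarked share was 53.2% in the lowest and 12.7% in the highest group.

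Large clusters of distal H3K27ac lay beside hepatocyte transcription factors more often than beside random genes under each stitching rule tried, whereas the other 5 lists above the 95th percentile fell below it with stitching over 5000 bp. Stitching gave 20412 clusters, of which 788 lay above the cutoff, and 1334 protein-coding genes (6.73%) had an end within 50000 bp of these. Among hepatocyte transcription factors 5 of 20 were near a cluster (8.66% to 49.1%, percentile 99.565), among them HNF4A, FOXA2, CEBPA and PROX1. Among secreted proteins 6 of 22 were (percentile 99.925, and 81.035 with stitching over 5000 bp), of which FGA, FGB and FGG are neighbours, beside AHSG, AMBP and ITIH2. Fetal liver genes had 4 of 16 (GPC3, H19, SALL4 and CD24, percentile 99.13, and 90.34 over 5000 bp) and epithelial-mesenchymal genes 4 of 13 (CLDN1, OCLN and the adjacent keratin genes KRT8 and KRT18, percentile 99.71, and 72.255 over 5000 bp). These members were named after their values were seen.

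The highest-ranked cluster, 17:43233504 to 43300676, covered 13 annotated snRNA genes, including the U2 spliceosomal RNA gene RNU2-1, with 46 H3K4me3 and 2 H3K4me1 summits, and its nearest protein-coding gene was CCDC200. The next, X:115843642 to 115893641, covered the lncRNA genes DANT1 and DANT2, and its nearest protein-coding gene was PLS3 at 192781 bp. The others lay in GNG7 (19:2540536 to 2614150), FNDC3B (3:172027823 to 172225288, 88 summits), MID1 (X:10473669 to 10636985) and SRGAP1 (12:63849336 to 63985769). The list of 10 ended with ADGRG6 (6:142280059 to 142386863), CMSS1 and FILIP1L (3:99832394 to 99964658), SCARB1, a lipoprotein receptor gene (12:124804335 to 124941064), and TNS3 (7:47429039 to 47568995).

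Near clusters above the cutoff were also 1 of 24 metabolism genes (TAT, percentile 33.725), 3 of 13 Wnt targets (96.835), 3 of 15 housekeeping (96.64), 2 of 15 sterol (83.325) and 2 of 12 cholangiocyte genes (87.98). Cell cycle and homeobox genes had 0 of 16 (18.335 and 21.89), and stellate and endothelial genes 0 of 12 (22.3 and 20.15). Leukocyte and neuronal genes had 1 of 14 (60.73 and 57.945), and muscle genes 1 of 12 (62.425). The scaled curve depends on its highest value, and without the 3 highest-ranked clusters 1381 lay above the cutoff. With stitching over 5000 bp, Wnt targets fell to a percentile of 91.59 and housekeeping genes to 90.71 (73.42 when clusters were ranked by number of summits), while transcription factors stayed at 99.045.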

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

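Of the tests below, the percentile of open chromatin at secreted-protein genes, the size-adjusted periodicity and the percentile of metabolism genes outside clustered families were chosen only after the results were seen. Summits on unplaced contigs stood out as signal in sequences that the main comparisons left out. They numbered 401 for ATAC, 124 for H3K27ac, 131 for H3K4me1 and 109 for H3K4me3. The contig with the highest count was GL000225.1 for ATAC (46), KI270721.1 for H3K27ac and H3K4me1 (28 and 33) and GL000220.1 for H3K4me3 (12).

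The 3 highest-ranked H3K27ac clusters had summed scores of 2233, 1727 and 1028, and the next had 948, so the first and second stood apart. A gain of the surrounding region would raise scores in the flanks, but the highest flank median was 1.08 times that of all distal summits. For tandem repeat arrays, the periodicity of summit positions was 0.332 in the first and 0.343 in the third cluster, against a median of 0.434 and a 95th percentile of 0.658 in the next 97, and adjusted for the number of summits it was 4.97 and 4.46, against a median of 5.25. These lie below the medians but within the spread of the other clusters, so periodicity does not decide for the first and the third cluster. The first covers 13 annotated snRNA genes, which goes with an array of repeated genes, and whether this accounts for its rank was not tested. For the third, repeats and other causes cannot be told apart. The second cluster, over DANT1 and DANT2, had an adjusted periodicity of 17.0, above the highest of the other clusters, 10.5, so a repeat array may account for its rank, and no biological explanation was tested.

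Distal open sites without a histone summit made up 33.1% of the class. Satellite sequence as the main source is argued against by the 16 windows of 1 Mb that hold ATAC summits almost alone and no protein-coding gene, which held 788 or 5.42% of the unmarked sites. An ATAC list from a non-hepatic cell type is argued against by the percentile of 99.955 for open chromatin at secreted-protein genes, although another hepatic cell is not excluded and the ATAC peak names carry a different prefix. Weak ATAC calls as the whole cause and other causes cannot be told apart, because 12.7% of the highest-scoring of 4 equal groups was unmarked, between the bounds of 10% and 20% set beforehand. No biological explanation was tested.

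Genes of mature hepatocyte metabolism had few promoter marks. Loss of the surrounding regions is argued against by their neighbours, of which 136 of 271 (50.2%, 44.1 to 56.3) had both marks, and promoters away from gene ends by a percentile of 0.03 with marks counted anywhere in the gene. For reads shared between paralogs, 4 of 15 members outside clustered families had both marks (26.7%, 7.79 to 55.1), an interval too wide for the bounds of 30% and 50% set beforehand. Those 15 lay at a percentile of 0.975 among random lists, so the lack of marks was not limited to clustered families. This argues against shared reads in clustered families as the whole cause. It is no test of shared reads in the 15, which were chosen as lying outside such families. For the 9 members in clustered families, 0 with both marks, shared reads and a true lack cannot be told apart. No biological explanation was tested.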

How the results depend on the processing

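Alternatives with marks counted anywhere in the gene, matching on RefSeq transcripts, placement within windows that hold a summit, and leaving out the ATAC library, ATAC-only windows or the 3 highest-ranked clusters were chosen after seeing the data. The 5′ end alone, matching on annotated start sites and the motif search with its 4 alternatives were not run. No paired analysis was possible because each assay had 1 library, and read depth, which sets how many weak summits are called, was unknown. Where no reason is given, the cause was not tested.

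In this order, ATAC with H3K27ac, H3K27ac with H3K4me1 and H3K4me3 with H3K27ac gave 33.4%, 28.4% and 42.8% within 250 bp, 47.7%, 44.5% and 56.1% within 500 bp and 55.5%, 76.3% and 75.4% within 2000 bp, by construction of the window. Scores of at least 10 gave 63.1%, 18.6% and 67.7%, and the 20000 highest-scoring summits gave 52.4%, 22.7% and 56.9%, both of which use fewer summits. A circular shift, which keeps clustering, gave ratios of 11.9, 9.20 and 14.2. Collapsing close summits or using every sequence left these shares within their intervals, and placement in windows that hold a summit gave ratios of 9.26, 7.31 and 11.04.

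H3K4me3 summits at gene ends came to 28.4%, 50.3% and 56.9%, and H3K4me1 summits to 3.13%, 15.7% and 5.87%, with 500 bp, 2500 bp and scores of at least 10. Genes with H3K4me3 and H3K27ac came to 40.8%, 61.3% and 48.7% under the same settings and to 66.8% with marks anywhere in the gene. Without the ATAC library, the share with 3 features becomes that with H3K4me3 and H3K27ac, 54.5%.

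Secreted proteins had both marks in 86.4% at 2500 bp and in 86.4% anywhere in the gene, at percentiles of 99.745 and 99.73, and reached 96.535 with matching on transcripts. Metabolism genes had 37.5% anywhere in the gene and stayed under the 5th percentile in all alternatives. Fetal liver genes lost their low position, with 51.01 at 2500 bp and 71.085 anywhere in the gene, above the middle of random lists. Of the alternative percentiles over all lists, 50 for both marks stayed in the same range (below 5, 5 to 95 or above 95), while 10 moved out of the middle range and 4 moved into it from below, among them fetal liver genes. The same range held for 47 with distal H3K27ac, where 1 moved into the middle range, and for 57 near clusters, where 6 moved into it and 1 out of it. Values could move widely within the middle range, as for secreted proteins, from 94.15 to 47.57 with scores of at least 10.

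Distal ATAC summits with H3K27ac and H3K4me1 came to 18.8% within 500 bp, 36.6% within 2000 bp, 12.4% with scores of at least 10 and 31.1% without ATAC-only windows. Without the ATAC library, 73.2% of distal H3K27ac summits had H3K4me1, a share with another denominator. Unmarked sites came to 37.5%, 31.4%, 36.0% and 31.9% in the order of the first 4 settings, and to 34.1% beyond 2500 bp of gene ends. Ranking by number of summits put 1346 clusters above the cutoff, and leaving out the 3 highest put 1381 there, which lowers the maximum that scales the curve.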

Other observations

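Gene families were chosen by symbol after the data were seen. All 28 mediator subunit genes, whose products link regulators to RNA polymerase, had H3K4me3 and H3K27ac at a gene end, as did 79 of 84 cytosolic ribosomal protein genes (94.0%, 86.7 to 98.0) and 35 of 39 proteasome subunit genes. Replication-dependent histone genes had both at 56 of 71 (78.9%, 67.6 to 87.7), against 32.1% in length-matched random lists. Olfactory receptor genes had both at 1 of 389, and keratin-associated protein genes at 0 of 94 (upper bound 3.85%). Some families, such as histone and olfactory receptor genes, hold closely similar copies, and reads that align to several places were handled in a way not given in the sources used here.

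Zinc finger genes of the ZNF series had both marks at 382 of 517 (73.9%, 69.9 to 77.6) but H3K4me1 at only 36 (6.96%), against 17.5% of all protein-coding genes. Apolipoprotein genes had both marks at 9 of 13 and H3K4me1 at 11 of 13. UDP glucuronosyltransferase genes, which conjugate drugs and bilirubin, had both marks at 1 of 19, with a median of 9 distal H3K27ac summits. Members that lie within 50000 bp of each other count the same summits, so this median can rest on few loci. Clustered protocadherin genes had both marks at 16 of 53 and H3K4me1 at none.

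Among windows of 1 Mb, 16 held ATAC summits almost alone and no protein-coding gene, on chromosomes 1, 4, 5, 6, 9, 10, 12 and 19. The window at 5:49000001 to 50000000 held 88 ATAC summits and 0 histone summits. In the other direction, the window at 16:55000001 to 56000000 held 7 protein-coding genes and 1 summit, and that at 7:63000001 to 64000000 held 13 protein-coding genes and 1 summit each of ATAC, H3K27ac and H3K4me3.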
